A study of Homo sapiens with 9 samples.

How the data were processed

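The series holds RNA sequencing of H1299 cells transfected with a control siRNA or with either of 2 siRNAs against FOXN3. Per the labels' protocols, cells at 30 to 50% density were transfected with 50 nM siRNA by Lipofectamine RNAiMAX, RNA was extracted with TRIzol, and polyadenylated RNA went into libraries with an NEBNext Ultra RNA kit, which does not mark strand. Groups were taken from the sample titles, which name siControl, siFOXN3-1 and siFOXN3-2 with 3 replicates each. The treatment labels of siFOXN3-2 replicates 2 and 3 name siFOXN4 and siFOXN5 instead, while their titles and table columns continue the siFOXN3-2 series. FOXN3 was low in these 2 samples as in siFOXN3-2 replicate 1. Nothing in the labels says that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

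The values used were the FPKM deposited by the authors, 1 table of 34789 Ensembl genes and 9 columns with 1 column per sample. Per the submitters' processing notes, reads were processed with fastp 0.14.0, HISAT2 2.1.0 and StringTie 1.3.3b on GRCh38. The annotation release, the counting options and any filter are not given in the sources used here. Low FPKM values of a gene were whole multiples of a step that scaled with depth, and exon lengths of GENCODE 29 turned these steps into a depth per sample. Of 4421 genes with small steps, 3764 (85.1%) gave the same depth for a sample, and 98.2% of the values worth 1 to 50 reads were whole within 0.05. The depth was 17.0 to 19.6 M fragments per sample, and whole reads could be recovered for 12674 (99.7%) of the tested genes. Replicates differed by more than read sampling, with a mean chi-square per gene of 3.90 to 12.8 over pairs of samples of the same group. Symbols were matched for 34435 genes (99.0%), and 354 had none.

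The comparisons, lists, named-gene rule and first alternatives were set before the data were examined. FPKM were transformed to log2 with a pseudocount of 1, and genes with a mean of at least 1 FPKM over the 9 samples were tested (12707, with 22082 left out). A model with 3 groups was fitted with limma 3.58.1 in R 4.3.3 with empirical Bayes moderation and a mean-variance trend (6 residual and 4.02 prior degrees of freedom). The 4 contrasts were each siRNA against siControl, the average of both against siControl, and siFOXN3-2 against siFOXN3-1. Tests were two-sided, and p-values were adjusted over all tested genes by the Benjamini-Hochberg method, with 0.05 as the threshold. Exact permutation tests of FOXN3 used the log2 values. Figures and motif counts were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

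Of 30 fixed lists, 26 had a test with limma's camera at a preset correlation of 0.01, for which at least 5 members had to be tested, and each was also tested with an estimated correlation. The lists covered the study genes, homologous recombination, Fanconi anaemia, end joining, base excision, nucleotide excision and mismatch repair, damage checkpoint, p53 targets, DNA replication, mitosis, interferon response, NF-κB and inflammation, and unfolded protein and ATF4. Others covered cholesterol synthesis, glycolysis and hypoxia, TGF-β and matrix, Wnt targets, apoptosis, ribosome biogenesis, ribosomal proteins, oxidative phosphorylation, mitochondrially encoded genes, immediate early genes, autophagy and lysosome, and oxidative stress. The other 4 held markers of immune, fibroblast, endothelial and lung epithelial cells. A camera test compares a list with all other genes, so its direction is relative to their average. Genes named in the text were the study genes and, for each comparison, the 6 called genes with the largest rise and the 6 with the largest fall among genes with a symbol and without overlap between groups. The 8 rises and 8 falls largest with both siRNAs and up to 4 members of each list with the smallest adjusted p were also named. Genes named for other reasons are marked where they appear. Some genes that this rule named are not reported here.

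Alternatives were the pseudocount, other filters on mean FPKM, scaling by median ratios, by the sum of FPKM or by quantiles, eBayes without a trend or with robust moderation, only the compared groups in the fit, a log2 threshold of 1, the replicate number as a block, and leaving out each sample. Added after seeing the data were a correction for GC content alone and with the block, voom on the recovered reads, and protein-coding genes only. For 3' UTR motifs, 16173 7-mers were counted in 10576 genes, with the fold changes adjusted for UTR length, GC content and mean expression, and z compared with 200 permutations of genes. The gene, list and motif tests were tested on simulated data. Of genes changed by 0.5, 1 and 2 on the log2 scale among 12707, 76.7, 98.4 and 99.7% were recovered for siFOXN3-1 and 83.1, 95.9 and 100% for siFOXN3-2, with 4.82 and 4.20% false calls. The list test recovered 10 of 10 shifted lists and called 0 of 250 others, and the motif count recovered 10 of 10 planted motifs at falls of 0.1 and of 0.2. Noise in the gene and list simulations was independent between genes, and few genes were changed. They do not show how the list test fares where members correlate, as estimated at 0.614 for ribosomal protein and 0.749 for mitochondrially encoded genes.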

Results

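RNA was sequenced from H1299 cells, an epithelial-like line of human non-small cell lung cancer that lacks the tumour suppressor p53. The cells had been transfected with a control siRNA (siControl) or with either of 2 siRNAs against FOXN3 (siFOXN3-1 and siFOXN3-2), each at 50 nM, and each of the 3 groups held 3 samples. The deposited table gave FPKM for 34789 genes in 9 samples. The whole-read steps of its low values placed the depth between 17.0 and 19.6 M fragments per sample, with means of 19.2 ± 0.447 M in siControl, 18.3 ± 0.802 M with siFOXN3-1 and 17.8 ± 0.747 M with siFOXN3-2 (SD, n = 3 per group). FPKM was above 0 for 26628 ± 138 genes in siControl, 25183 ± 361 with siFOXN3-1 and 25331 ± 231 with siFOXN3-2. Mitochondrially encoded genes held 13.7 ± 0.525% of the summed FPKM in siControl, 8.24 ± 0.891% with siFOXN3-1 and 7.99 ± 0.937% with siFOXN3-2. Across genes, which are not independent replicates, the log2 values of replicates correlated at 0.989 to 0.993 within a group. The correlation was 0.976 to 0.982 between the 2 FOXN3 siRNAs and 0.930 to 0.942 between either of them and siControl.

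FOXN3, the targeted gene, encodes a forkhead transcriptional repressor (ENSG00000053254, GRCh38 chromosome 14, 89124871 to 89619149). Its level was 4.85, 5.25 and 5.00 FPKM in the siControl samples, 1.28, 1.24 and 1.16 FPKM with siFOXN3-1, and 0.858, 0.958 and 1.06 FPKM with siFOXN3-2. The group means were 5.03 ± 0.203 FPKM in siControl, 1.22 ± 0.0593 FPKM with siFOXN3-1 and 0.958 ± 0.1001 FPKM with siFOXN3-2 (SD, n = 3 each), which left 24.3% and 19.0% of the siControl level. The log2 fold change was -1.44 (SE 0.0708, limma adjusted p = 1.42e-07) with siFOXN3-1 and -1.62 (SE 0.0708, adjusted p = 8.16e-08) with siFOXN3-2. The pseudocount of 1 FPKM damps these values, and voom on the recovered reads gave -2.04 and -2.39. A two-sided exact permutation test gave p = 0.1 for each siRNA, the smallest that 3 samples against 3 allow, and p = 0.0238 for the 6 siRNA samples against the 3 controls, the smallest for that design. FOXN3 did not pass the test between the 2 siRNAs (log2 fold change -0.18, adjusted p = 0.0659). FOXN3 exons share 282 bases with other genes on the same strand and 832 bases on the opposite strand, and the library kit did not mark strand.

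The series title names FOXN3 with β-TrCP, RSK2 and BRCA1. BRCA1, a scaffold of homologous recombination repair, fell from 4.21 ± 0.0926 FPKM in siControl to 1.705 ± 0.0697 FPKM with siFOXN3-1 and 1.66 ± 0.1295 FPKM with siFOXN3-2 (SD, n = 3). BTRC, which encodes the ubiquitin ligase subunit β-TrCP, fell from 4.78 ± 0.405 to 1.94 ± 0.304 and 1.58 ± 0.138 FPKM. RPS6KA3, the gene of the kinase RSK2, rose from 12.2 ± 0.585 to 17.4 ± 1.29 and 16.9 ± 1.54 FPKM. FOXN2, a paralog of FOXN3, rose from 6.86 ± 0.124 to 8.99 ± 0.628 and 10.3 ± 1.11 FPKM. FBXW11, the paralog of BTRC, had 21.4, 22.4 and 22.6 FPKM, and SIN3A, a co-repressor scaffold, had 8.801, 7.75 and 8.53 FPKM, and neither passed the test with either siRNA. FOXN1 and FOXN4 lay below the expression filter. The log2 fold changes of BRCA1 were -0.95 (limma adjusted p = 1.31e-06) and -0.97 (adjusted p = 1.24e-06), and those of BTRC -0.98 (adjusted p = 9.04e-06) and -1.16 (adjusted p = 3.21e-06). Those of RPS6KA3 were 0.48 (adjusted p = 3.19e-04) and 0.44 (adjusted p = 5.45e-04). As a list, these study genes (7 tested, with 2 higher and 3 lower with each siRNA) did not pass the list test, with adjusted p = 0.766 for siFOXN3-1 and 0.723 for siFOXN3-2.

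**Figure D1:**
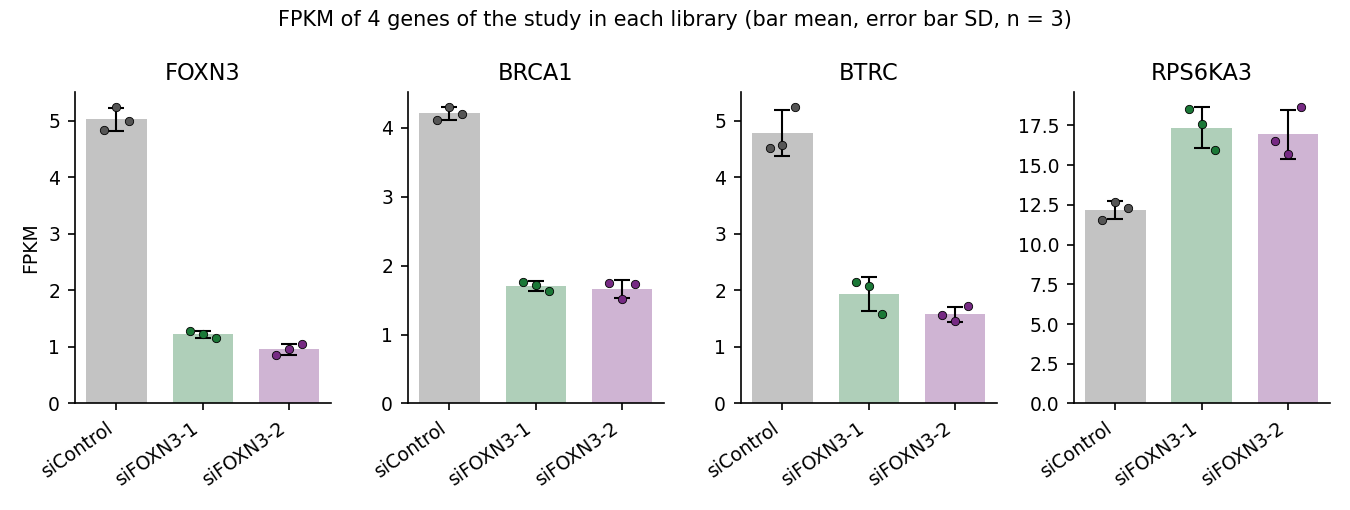
FPKM of FOXN3, BRCA1, BTRC and RPS6KA3 in siControl, siFOXN3-1 and siFOXN3-2 samples, with bars for the mean, error bars for the SD and points for the 3 samples of each group. FOXN3 averaged 5.03, 1.22 and 0.958 FPKM and BRCA1 4.21, 1.705 and 1.66 FPKM, whereas RPS6KA3 was higher with both siRNAs, at 17.4 and 16.9 FPKM against 12.2 FPKM.

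The comparison of siFOXN3-1 with siControl asked which transcripts changed when FOXN3 was lowered by this siRNA. Ranked here and below by log2 fold change with a pseudocount of 1 FPKM, which damps changes at low levels, the largest rises were in EGR1, an immediate early transcription factor, from 5.94 ± 1.07 to 94.8 ± 2.01 FPKM, and HILPDA, a hypoxia-inducible lipid droplet protein, from 10.6 ± 0.634 to 157 ± 5.83 FPKM (SD, n = 3). ZFP36, whose protein binds AU-rich elements and promotes mRNA decay, rose from 24.9 ± 1.97 to 299.6 ± 17.9 FPKM. DUSP5, a phosphatase of ERK kinases, rose from 27.2 ± 1.73 to 289.7 ± 6.195 FPKM, ADM, the gene of the peptide adrenomedullin, from 9.27 ± 1.05 to 103 ± 4.27 FPKM, and KRTAP2-3, a keratin-associated protein gene with close paralogs, from 0.281 ± 0.1896 to 12.9 ± 2.19 FPKM. The largest falls were in ACP2, a lysosomal acid phosphatase, from 8.34 ± 0.145 to 0.971 ± 0.157 FPKM, and HPS6, a factor of lysosome-related organelles, from 12.1 ± 0.474 to 1.902 ± 0.262 FPKM. The Integrator subunit INTS5 fell from 10.4 ± 0.758 to 1.62 ± 0.169 FPKM, CENPBD1P from 6.93 ± 0.448 to 0.836 ± 0.1002 FPKM, TMEM203 from 38.1 ± 2.65 to 8.53 ± 0.116 FPKM and the arginine methyltransferase PRMT6 from 8.22 ± 0.387 to 1.298 ± 0.113 FPKM.

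Immediate early genes formed the list with the strongest rise with siFOXN3-1. Of 30 tested, 25 rose and 2 fell, with a median log2 fold change of 1.66 (camera adjusted p = 3.23e-19, and adjusted p = 0.0412 with an estimated correlation). The nuclear receptor NR4A2 rose from 9.08 ± 0.912 to 79.3 ± 2.36 FPKM and the transcription factor KLF6 from 19.8 ± 0.619 to 72.01 ± 1.61 FPKM. Of 29 glycolysis and hypoxia genes, 24 rose and 1 fell (median 0.58, adjusted p = 4.1e-15, and adjusted p = 0.0412 with an estimated correlation). They included the glucose transporters SLC2A3, from 74.3 ± 5.53 to 445 ± 18.5 FPKM, and SLC2A1, from 36.9 ± 2.19 to 91.3 ± 1.78 FPKM. The secreted lipase inhibitor ANGPTL4 rose from 82.9 ± 3.596 to 429.7 ± 22.6 FPKM and the glycolytic enzyme ALDOA from 20.8 ± 1.05 to 65.4 ± 2.18 FPKM. Of 16 NF-κB and inflammatory genes, 11 rose and 2 fell (median 0.44, adjusted p = 1.03e-05, and adjusted p = 0.0412 with an estimated correlation), among them IER3, a stress response gene, from 79.6 ± 3.28 to 597 ± 27.1 FPKM and the cytokine LIF from 9.92 ± 1.43 to 73.7 ± 6.98 FPKM. TRAF1, a signalling adaptor of the same list, fell from 4.07 ± 0.169 to 2.97 ± 0.296 FPKM.

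The NRF2, unfolded protein, p53 target and cholesterol lists went up relative to other genes with siFOXN3-1 at the preset correlation, with members in both directions. Of 23 genes of the oxidative stress and NRF2 list, 15 rose and 3 fell (median 0.23, adjusted p = 2.36e-04, and adjusted p = 0.197 with an estimated correlation). OSGIN1, an oxidative stress-induced growth inhibitor, rose from 6.01 ± 0.574 to 37.8 ± 1.503 FPKM, while KEAP1, the negative regulator of NRF2, fell from 29.3 ± 1.37 to 16.2 ± 1.45 FPKM. Of 33 unfolded protein and ATF4 genes, 15 rose and 10 fell (median 0.16, adjusted p = 0.00131, and adjusted p = 0.269 with an estimated correlation). ATF3, a stress-induced transcription factor, rose from 1.46 ± 0.151 to 11.6 ± 0.484 FPKM, and SEL1L, an adaptor of endoplasmic reticulum-associated degradation, fell from 16.5 ± 0.756 to 9.898 ± 0.337 FPKM. Of 26 targets of p53, measured in a line without p53, 11 rose and 6 fell (median 0.07, adjusted p = 0.0125, and adjusted p = 0.137 with an estimated correlation). They included the cell cycle inhibitor CDKN1A, from 30.3 ± 0.806 to 100.2 ± 3.93 FPKM, and the growth arrest gene GADD45A, from 32.5 ± 2.34 to 151 ± 11.2 FPKM, whereas the apoptosis effector BAX fell from 11.9 ± 0.381 to 8.41 ± 0.871 FPKM. Of 24 cholesterol synthesis genes, 11 rose and 6 fell (median 0.06, adjusted p = 0.00285, and adjusted p = 0.269 with an estimated correlation). INSIG1, a sterol-regulated retention protein, rose from 44.6 ± 0.813 to 301 ± 5.59 FPKM, and the sterol reductase TM7SF2 fell from 22.3 ± 1.37 to 7.94 ± 0.309 FPKM.

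Matrix and Wnt genes split by member with siFOXN3-1. Of 35 TGF-β, epithelial-mesenchymal and matrix genes, 16 rose and 13 fell (median 0.14, adjusted p = 0.0125, and adjusted p = 0.335 with an estimated correlation). CCN1, a matricellular growth regulator, rose from 98.7 ± 4.63 to 804 ± 39.5 FPKM. LTBP2, a latent TGF-β binding protein, fell from 28.2 ± 2.38 to 12.4 ± 0.8902 FPKM. Of 13 Wnt targets, 7 rose and 4 fell (median 0.29, adjusted p = 0.0353, and adjusted p = 0.166 with an estimated correlation). The growth regulator MYC rose from 32.5 ± 0.744 to 144 ± 17.01 FPKM, and CTNNB1, which encodes β-catenin, fell from 33.4 ± 0.395 to 24.1 ± 0.445 FPKM. Of 37 autophagy and lysosome genes, 12 rose and 11 fell (median 0.07, adjusted p = 0.0353, and adjusted p = 0.149 with an estimated correlation), with the autophagy receptor SQSTM1 rising from 52.9 ± 0.641 to 93.8 ± 7.82 FPKM and the proton pump subunit ATP6V1A falling from 16.02 ± 0.671 to 10.1 ± 0.705 FPKM. Of 51 cytosolic ribosomal protein genes, whose reads can be shared with pseudogenes, 9 rose and none fell (median 0.11, adjusted p = 3.55e-04, and adjusted p = 0.525 with an estimated correlation), and adjusted over the list alone none passed. Under quantile normalization the median of the ribosomal protein list turned to -0.11.

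DNA replication genes fell with siFOXN3-1. Of 42 tested, 35 fell and 2 rose, with a median log2 fold change of -0.75 (adjusted p = 1.03e-05, and adjusted p = 0.155 with an estimated correlation). The replicative helicase subunits MCM3 and MCM6 fell from 47.8 ± 1.07 to 23.7 ± 1.63 FPKM and from 48.1 ± 1.15 to 23.6 ± 0.671 FPKM. PCNA, the sliding clamp, fell from 89.7 ± 7.93 to 45.6 ± 3.47 FPKM, and the polymerase α subunit POLA1 from 11.2 ± 0.629 to 5.52 ± 0.0741 FPKM. Of 39 homologous recombination genes, 29 fell and 2 rose (median -0.44, adjusted p = 8.37e-04, and adjusted p = 0.197 with an estimated correlation). All 13 mitochondrially encoded messenger RNA genes fell (median -1.09, adjusted p = 6.09e-04, and adjusted p = 0.335 with an estimated correlation), with cytochrome b, MT-CYB, dropping from 1791 ± 70.9 to 579.9 ± 55.3 FPKM. Of 21 base excision repair genes, 16 fell and 2 rose (median -0.35, adjusted p = 0.0224, and adjusted p = 0.149 with an estimated correlation). The flap nuclease FEN1 fell from 28.7 ± 0.832 to 15.2 ± 0.223 FPKM, and PARP2, a sensor of strand breaks, rose from 7.62 ± 0.224 to 10.2 ± 0.555 FPKM. Of 19 mismatch repair genes, 12 fell and none rose (median -0.30, adjusted p = 0.0353, and adjusted p = 0.335 with an estimated correlation), and PMS2 dropped from 7.19 ± 0.228 to 3.14 ± 0.338 FPKM.

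The other lists did not pass the list test with siFOXN3-1, although members of each did. Of 19 Fanconi anaemia genes, 12 fell and 2 rose (median -0.52, adjusted p = 0.108). Of 25 damage checkpoint genes, 17 fell and 3 rose (median -0.34, adjusted p = 0.0763), with the fork protection factor TIMELESS lower at 10.3 ± 0.578 against 28.8 ± 0.405 FPKM and the kinase WEE1 higher at 8.02 ± 0.338 against 4.18 ± 0.164 FPKM. Of 17 end joining genes, 11 fell and none rose (median -0.36, adjusted p = 0.169), and of 22 nucleotide excision repair genes, 13 fell and 5 rose (median -0.27, adjusted p = 0.760). Of 25 interferon response genes, 17 fell and 2 rose (median -0.41, adjusted p = 0.0799), SAMD9 among them at 0.474 ± 0.1605 against 2.44 ± 0.243 FPKM. Mitosis genes (39 tested) counted 13 higher and 15 lower (adjusted p = 0.242), apoptosis regulators (30) 9 and 11 (adjusted p = 0.527), ribosome biogenesis (37) 12 and 12 (adjusted p = 0.169) and nuclear oxidative phosphorylation genes (48) 4 and 10 (adjusted p = 0.713). In those 4 lists the test pointed up, relative to the average of all other genes, while the list mean lay below 0 at -0.07, -0.10, -0.05 and -0.08, and the medians were -0.01, -0.13, 0.00 and -0.09. Adjusted over the list alone, member counts were as over all genes except for 17 lower base excision repair, 11 lower mismatch repair, 17 higher unfolded protein, 7 lower cholesterol, 1 higher and 5 lower oxidative phosphorylation genes and the ribosomal protein genes given above.

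With siFOXN3-1, limma placed 8220 of 12707 tested genes past an adjusted p of 0.05, of which 2458 were higher and 5762 lower. An absolute log2 fold change of at least 1 was reached by 354 of the higher and 533 of the lower genes. With the pseudocount of 1 FPKM this takes more than a 2-fold change in FPKM, most of all at low levels. The 3 samples of each group did not overlap for 9032 genes (71.1%), against 10% by chance. The median log2 fold change of all tested genes was -0.17, and scaling each sample by its median ratio moved it to 0.00 and gave 3979 higher and 3939 lower genes. Quantile normalization gave 3645 higher and 4179 lower, so directions of small changes are relative to the scale of the deposited values. Some named genes share exon sequence with other genes in these unstranded libraries, over 42.3% of the exon length of ALDOA and 17.4% of HILPDA on the same strand, and over 39.0% of XPC, 35.2% of ANKRD37, 30.1% of ACTA2, 26.5% of IER3 and 22.0% of SQSTM1 on the opposite strand.

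The comparison of siFOXN3-2 with siControl put the same question to a separate siRNA. The largest rises were in HILPDA, from 10.6 ± 0.634 to 147 ± 11.6 FPKM, EGR1, from 5.94 ± 1.07 to 72.2 ± 7.705 FPKM, and ADM, from 9.27 ± 1.05 to 107 ± 1.83 FPKM (SD, n = 3). CCN2, a matricellular protein also known as connective tissue growth factor, rose from 27.7 ± 0.701 to 286 ± 14.9 FPKM, ZFP36 from 24.9 ± 1.97 to 257 ± 9.66 FPKM, and SAT1, the rate-limiting enzyme of polyamine catabolism, from 21.8 ± 0.736 to 204 ± 30.6 FPKM. The largest falls among longer transcripts were in NTSR1, a neurotensin receptor, from 16.2 ± 0.811 to 2.79 ± 0.276 FPKM, TMEM185B, from 21.3 ± 0.802 to 4.73 ± 0.284 FPKM, and CENPBD1P, from 6.93 ± 0.448 to 1.05 ± 0.126 FPKM. The small RNA genes RNU6-1263P (from 9.96 ± 3.59 to 1.21 ± 0.7598 FPKM), MIR3939 (from 5.12 ± 1.96 to 0.526 ± 0.512 FPKM) and RNU6-26P (from 10.03 ± 4.39 to 2.29 ± 2.105 FPKM) also fell, with wide spread between replicates.

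Immediate early and hypoxia genes rose with siFOXN3-2. Of 30 immediate early genes, 23 rose and 1 fell (median 1.39, adjusted p = 3.28e-12, and adjusted p = 0.128 with an estimated correlation), with FOS, a component of the AP-1 factor, rising from 2.74 ± 0.246 to 31.6 ± 2.82 FPKM. Of 29 glycolysis and hypoxia genes, 22 rose and 4 fell (median 0.60, adjusted p = 1.36e-08, and adjusted p = 0.128 with an estimated correlation). MXI1, a MYC antagonist, rose from 9.76 ± 0.385 to 27.1 ± 0.646 FPKM, and the glycolytic enzyme PFKP fell from 46.2 ± 1.47 to 33.95 ± 3.19 FPKM. Of 24 cholesterol synthesis genes, 15 rose and 6 fell (median 0.39, adjusted p = 8.42e-04, and adjusted p = 0.286 with an estimated correlation). INSIG1 rose to 398 ± 31.1 FPKM, and the sterol oxidase MSMO1 from 16.4 ± 0.954 to 150.4 ± 14.2 FPKM. Of 23 oxidative stress and NRF2 genes, 14 rose and 3 fell (median 0.40, adjusted p = 2.16e-04, and adjusted p = 0.286 with an estimated correlation), with the thioredoxin reductase TXNRD1 rising from 49.4 ± 0.696 to 122 ± 7.46 FPKM and the transporter ABCC3 falling from 5.11 ± 0.233 to 1.36 ± 0.186 FPKM.

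Of 26 targets of p53, 14 rose and 6 fell with siFOXN3-2 (median 0.34, adjusted p = 0.00794, and adjusted p = 0.128 with an estimated correlation). CDKN1A reached 85.6 ± 4.203 FPKM and GADD45A 99.04 ± 12.8 FPKM, while the damage sensor DDB2 fell from 7.99 ± 0.0565 to 4.0 ± 0.109 FPKM. Of 33 unfolded protein and ATF4 genes, 17 rose and 10 fell (median 0.26, adjusted p = 0.00739, and adjusted p = 0.373 with an estimated correlation), with the co-chaperone DNAJB9 rising from 4.797 ± 0.279 to 20.7 ± 1.77 FPKM and SHMT2, a mitochondrial enzyme of serine metabolism, falling from 30.1 ± 1.71 to 9.66 ± 0.6101 FPKM. Of 16 NF-κB and inflammatory genes, 9 rose and 2 fell (median 0.29, adjusted p = 0.0169, and adjusted p = 0.257 with an estimated correlation), with IER3 at 283 ± 24.2 and LIF at 34.9 ± 1.16 FPKM.

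Replication, recombination and mitochondrially encoded genes fell with siFOXN3-2. Of 42 DNA replication genes, 30 fell and 6 rose (median -0.47, adjusted p = 0.00123, and adjusted p = 0.286 with an estimated correlation). MCM3 fell to 15.8 ± 0.109 FPKM and MCM4 from 63.1 ± 0.288 to 38.4 ± 0.555 FPKM. Of 39 homologous recombination genes, 24 fell and 3 rose (median -0.37, adjusted p = 0.0132, and adjusted p = 0.319 with an estimated correlation). All 13 mitochondrially encoded genes fell (median -1.16, adjusted p = 9.54e-05, and adjusted p = 0.373 with an estimated correlation), with MT-CYB at 589 ± 71.7 FPKM and the cytochrome oxidase subunit MT-CO3 dropping from 3376 ± 35.3 to 1389 ± 120.3 FPKM.

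The remaining lists did not pass the list test with siFOXN3-2. Fanconi anaemia genes counted 3 higher and 13 lower (adjusted p = 0.147), end joining 3 and 9 (adjusted p = 0.709), base excision repair 3 and 11 (adjusted p = 0.452), nucleotide excision repair 6 and 9 (adjusted p = 0.931), mismatch repair 5 and 8 (adjusted p = 0.723) and damage checkpoint 7 and 12 (adjusted p = 0.878). XPC, a nucleotide excision repair sensor, fell from 8.298 ± 0.279 to 3.805 ± 0.327 FPKM, while CDK7, the kinase of transcription factor TFIIH, rose from 30.5 ± 1.82 to 68.7 ± 7.81 FPKM. Interferon response genes counted 2 higher and 14 lower (adjusted p = 0.0933), mitosis genes 18 and 12 (adjusted p = 0.102) and apoptosis regulators 14 and 8 (adjusted p = 0.0858). The mitotic kinase CDK1 rose from 54.4 ± 2.698 to 111 ± 15.1 FPKM, and the spindle protein ASPM fell from 13.1 ± 0.903 to 6.06 ± 0.544 FPKM. TGF-β and matrix genes counted 11 higher and 18 lower (adjusted p = 0.999), Wnt targets 4 and 4 (adjusted p = 0.903) and autophagy and lysosome genes 15 and 9 (adjusted p = 0.0762). Ribosome biogenesis counted 12 and 12 (adjusted p = 0.220), ribosomal protein genes 7 and 0 (adjusted p = 0.0714) and oxidative phosphorylation 7 and 8 (adjusted p = 0.536). Test, mean and median differed in sign for nucleotide excision repair (up, -0.05, -0.16), TGF-β and matrix (down, 0.03, -0.25), Wnt (up, 0.06, -0.10) and oxidative phosphorylation (up, -0.01, -0.01). Adjusted over the list alone, counts differed from those over all genes only for nucleotide excision repair (10 lower), replication (7 higher), unfolded protein (18 higher, 11 lower), Wnt (6 lower), ribosomal protein genes (none) and oxidative phosphorylation (3 higher, 5 lower).

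With siFOXN3-2, limma placed 8049 of 12707 genes past an adjusted p of 0.05, with 3066 higher and 4983 lower. An absolute log2 fold change of at least 1, with the pseudocount, was reached by 354 and 423 of these. The samples of the compared groups did not overlap for 8665 genes (68.2%), against 10% by chance. The median log2 fold change of all genes was -0.10, and median-ratio scaling moved it to -0.00 with 3912 higher and 3948 lower genes. Quantile normalization gave 3746 higher and 4145 lower.

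The average of both siRNAs against siControl asked which changes went with the loss of FOXN3 whichever siRNA was used. BRCA1 fell by 0.96 on the log2 scale (limma adjusted p = 3.72e-07). Of 39 homologous recombination genes tested, 26 fell, 3 rose and 10 did not pass. BRCC3, a deubiquitinase of a BRCA1 complex, fell from 6.96 ± 0.0839 to 2.398 ± 0.145 and 2.04 ± 0.383 FPKM, the Holliday junction resolvase GEN1 from 2.47 ± 0.0466 to 0.505 ± 0.119 and 0.545 ± 0.0463 FPKM, and EME1, a subunit of a structure-specific nuclease, from 11.4 ± 0.374 to 4.71 ± 0.136 and 4.898 ± 0.523 FPKM (SD, n = 3 per group). The median log2 fold change of the list was -0.41 (camera adjusted p = 0.00282, and adjusted p = 0.274 with an estimated correlation). The call also ended with a filter on a mean FPKM of at least 5 (median -0.30, adjusted p = 0.0867). Adjusted over the list alone, 3 members were higher and 26 lower.

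The gene changes were shared in large part by the 2 siRNAs. The 8 rises that were largest with both were in HILPDA, EGR1, ZFP36, ADM, SAT1, ANKRD37, FOS and H2BC21. The last encodes a histone H2B, and its level went from 9.25 ± 0.595 FPKM in siControl to 88.8 ± 1.65 and 78.6 ± 1.85 FPKM. ANKRD37, a hypoxia-induced ankyrin repeat gene, rose from 1.42 ± 0.232 to 22.1 ± 0.894 and 19.2 ± 2.11 FPKM. The largest shared falls were in CENPBD1P, C22orf46P, the pseudogene NOC2LP1, NTSR1, LINC02870, the antisense gene ZBTB46-AS1, HPS6 and the nuclear receptor coactivator NCOA5, which fell from 10.1 ± 0.375 to 2.404 ± 0.16 and 2.43 ± 0.435 FPKM. C21orf58 fell by 1.83 and PRMT6 by 1.82 on the log2 scale in the average of both. CCN1 and INSIG1 rose by 2.91 and 2.93 in the average, and HMGCS1, the cytosolic HMG-CoA synthase, rose from 18.3 ± 0.1102 to 90.3 ± 3.16 and 105 ± 4.18 FPKM.

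In the average of both siRNAs, 11 of 26 lists passed the list test, 8 up and 3 down relative to other genes. Besides homologous recombination, DNA replication (2 higher, 33 lower, median -0.64, adjusted p = 1.42e-04) and mitochondrially encoded genes (0 higher, 13 lower, median -1.12, adjusted p = 2.29e-04) went down. The lists that went up were immediate early (25 higher, 1 lower, median 1.52), glycolysis and hypoxia (22 and 3, median 0.64), NF-κB (10 and 2, median 0.26), NRF2 (15 and 3, median 0.32), cholesterol (12 and 6, median 0.22), unfolded protein (18 and 11, median 0.34), p53 targets (14 and 7, median 0.22) and ribosomal protein genes (9 and 0, median 0.08). Their adjusted p-values were 1.28e-15, 9.78e-12, 2.93e-04, 1.42e-04, 0.00125, 0.00282, 0.00669 and 0.00312 in that order. With an estimated correlation none of the 11 passed. The adjusted p was then 0.232 for replication and 0.358 for mitochondrially encoded genes, and 0.0804, 0.0804, 0.0980, 0.232, 0.274, 0.306, 0.102 and 0.594 for the lists that went up. Under quantile normalization the ribosomal protein median was -0.10. TGF-β and matrix genes did not pass (adjusted p = 0.191) and had a median of -0.05 and a mean of 0.12.

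The average of both called 8589 genes, 2878 higher and 5711 lower, and median-ratio scaling gave 4161 higher and 4209 lower. Groups did not overlap for 6783 genes (53.4%), against 2.38% by chance. With both siRNAs and in the same direction, 6183 genes passed, 1941 higher and 4242 lower, where independent lists would share 593 and 2260. Median-ratio scaling gave 2993 higher and 3008 lower shared genes. A further 185 genes passed with both in opposite directions, 1852 with siFOXN3-1 alone and 1681 with siFOXN3-2 alone. Fold changes against siControl correlated at 0.870 across genes (covariance 0.252), and 20 simulations of unchanged groups against the same controls gave 0.503 (covariance 0.00604) and at most 0 genes called with both. The covariance difference of 0.246 is what the spread within groups does not account for. It includes any difference in handling of the siControl cells. Independent lists leave out the controls that both comparisons use, so part of the excess over them may come from these 3 samples, which are too few to divide.

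**Figure D2:**
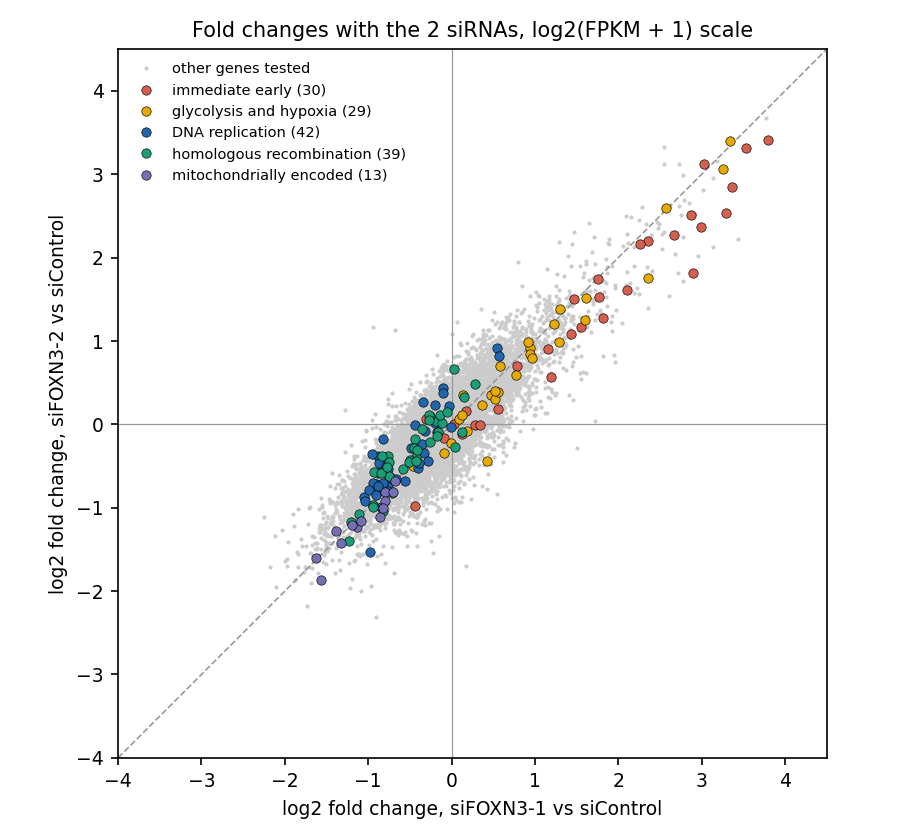
Log2 fold change with siFOXN3-1 (horizontal) and siFOXN3-2 (vertical) against siControl for 12707 genes, with 5 gene lists coloured. The fold changes correlated at 0.870, with 25 and 23 of 30 immediate early genes higher and 13 of 13 mitochondrially encoded genes lower.

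The comparison of siFOXN3-2 with siFOXN3-1 asked where 2 siRNAs against the same gene differed. SLC25A5, an ADP/ATP carrier of the inner mitochondrial membrane with many pseudogenes, had 308 ± 12.4 FPKM in siControl and 349 ± 30.2 FPKM with siFOXN3-1 but 94.5 ± 10.97 FPKM with siFOXN3-2 (SD, n = 3). The cytokine IL11 had 2.57 ± 0.175, 10.8 ± 0.0738 and 2.67 ± 0.0187 FPKM, the capping protein regulator MTPN 49.96 ± 0.422, 73.7 ± 5.52 and 27.6 ± 2.89 FPKM, and SHMT2 30.1 ± 1.71, 25.7 ± 0.573 and 9.66 ± 0.6101 FPKM. Higher with siFOXN3-2 than with siFOXN3-1 were ACP2, at 3.33 ± 0.174 against 0.971 ± 0.157 FPKM, and the inositol pyrophosphate kinase PPIP5K2, at 6.03 ± 0.304 against 2.32 ± 0.219 FPKM. The short RNA genes RN7SL5P (0.437, 3.64 and 0.172 FPKM), RNU6-1263P (9.96, 4.79 and 1.21 FPKM), Y_RNA (2.22, 0.359 and 2.54 FPKM) and SNORA71C (2.21, 4.49 and 11.2 FPKM) also differed. Their exon lengths are 102 to 321 bases, so the lowest of these values rest on very few reads, and Y_RNA is a symbol shared by other genes. S100A9, a calcium-binding protein of myeloid cells, was listed at 0 in all 3 siFOXN3-1 samples and averaged 0.938 ± 0.286 FPKM in siControl and 3.41 ± 0.985 FPKM with siFOXN3-2. The log2 difference was -1.88 for SLC25A5 (limma adjusted p = 3.51e-06), -1.68 for IL11 (adjusted p = 4.94e-07), -1.39 for MTPN (adjusted p = 9.76e-06) and 1.14 for ACP2 (adjusted p = 1.36e-05).

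Immediate early, NF-κB, matrix, hypoxia and Wnt lists were lower with siFOXN3-2 than with siFOXN3-1. Of 30 immediate early genes, 20 were lower and 1 higher (median -0.32, adjusted p = 4.08e-11, and adjusted p = 0.0861 with an estimated correlation), among them IER3, at 283 ± 24.2 against 597 ± 27.1 FPKM. Of 16 NF-κB genes, 10 were lower (median -0.28, adjusted p = 1.77e-06, and adjusted p = 0.0861 with an estimated correlation), with LIF at 34.9 ± 1.16 against 73.7 ± 6.98 FPKM. TGF-β and matrix genes counted 16 lower and 2 higher (median -0.17, adjusted p = 1.77e-06, and adjusted p = 0.213 with an estimated correlation). CCN2 of this list went the opposite way, at 286 ± 14.9 against 167 ± 3.32 FPKM. Glycolysis and hypoxia genes counted 9 lower and 1 higher (median -0.12, adjusted p = 2.46e-05, and adjusted p = 0.186 with an estimated correlation). Wnt targets counted 6 lower and 1 higher (median -0.07, adjusted p = 0.00263, and adjusted p = 0.0861 with an estimated correlation), with the cyclin CCND1 at 58.4 ± 4.32 against 119.6 ± 3.63 FPKM. Of 51 ribosomal protein genes, 1 was lower (RPL35, 337 ± 23.9 against 389 ± 25.8 FPKM), with a median of -0.03 (adjusted p = 0.00992, and adjusted p = 0.807 with an estimated correlation) that turned to 0.05 under quantile normalization. NRF2 genes (9 higher and 1 lower, adjusted p = 0.352), unfolded protein genes (10 and 6, adjusted p = 0.873) and p53 targets (9 and 7, adjusted p = 0.848) did not pass as lists.

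Cholesterol, base excision repair, damage checkpoint, DNA replication and mismatch repair lists were higher with siFOXN3-2 than with siFOXN3-1. Of 24 cholesterol genes, 16 were higher and 1 lower (median 0.30, adjusted p = 0.00483, and adjusted p = 0.360 with an estimated correlation), with the sterol carrier STARD4 at 30.02 ± 2.15 against 18.3 ± 2.71 FPKM. Base excision repair counted 12 higher and 0 lower (median 0.22, adjusted p = 0.00483, and adjusted p = 0.0861 with an estimated correlation). Damage checkpoint counted 14 and 2 (median 0.26, adjusted p = 0.00909, and adjusted p = 0.293 with an estimated correlation), with the clamp subunit RAD1 at 5.69 ± 0.479 against 2.99 ± 0.146 FPKM. DNA replication counted 20 and 1 (median 0.19, adjusted p = 0.0191, and adjusted p = 0.432 with an estimated correlation), with PCNA at 69.5 ± 4.35 against 45.6 ± 3.47 FPKM. Mismatch repair counted 9 and 0 (median 0.20, adjusted p = 0.0456, and adjusted p = 0.438 with an estimated correlation). Homologous recombination genes counted 17 higher and 1 lower and did not pass as a list (median 0.13, adjusted p = 0.120), and BRCA1 did not differ past the test (log2 difference -0.02, adjusted p = 0.794). Nor did Fanconi anaemia (adjusted p = 0.352), end joining (adjusted p = 0.145) and nucleotide excision repair genes (adjusted p = 0.259) pass as lists. None of the 13 mitochondrially encoded genes passed between the siRNAs (list adjusted p = 0.120). Adjusted over the list alone, counts were as over all genes for immediate early, NF-κB, glycolysis, Wnt, cholesterol and checkpoint genes, and were 12 higher and 1 lower for the base excision and also for the mismatch repair list, 21 and 2 for replication, 3 and 16 for matrix genes and 0 for ribosomal protein genes.

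Limma called 4590 of 12707 genes between the 2 siRNAs, 3227 higher and 1363 lower with siFOXN3-2. Only 11 of the higher and 34 of the lower ones differed by at least 1 on the log2 scale with the pseudocount, and 3759 differed by less than 0.5. The median of all genes was 0.08, and median-ratio scaling moved it to 0.01 with 1942 higher and 1982 lower genes. The samples of the 2 siRNAs did not overlap for 5839 genes (46.0%), against 10% by chance.

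**Figure D3:**
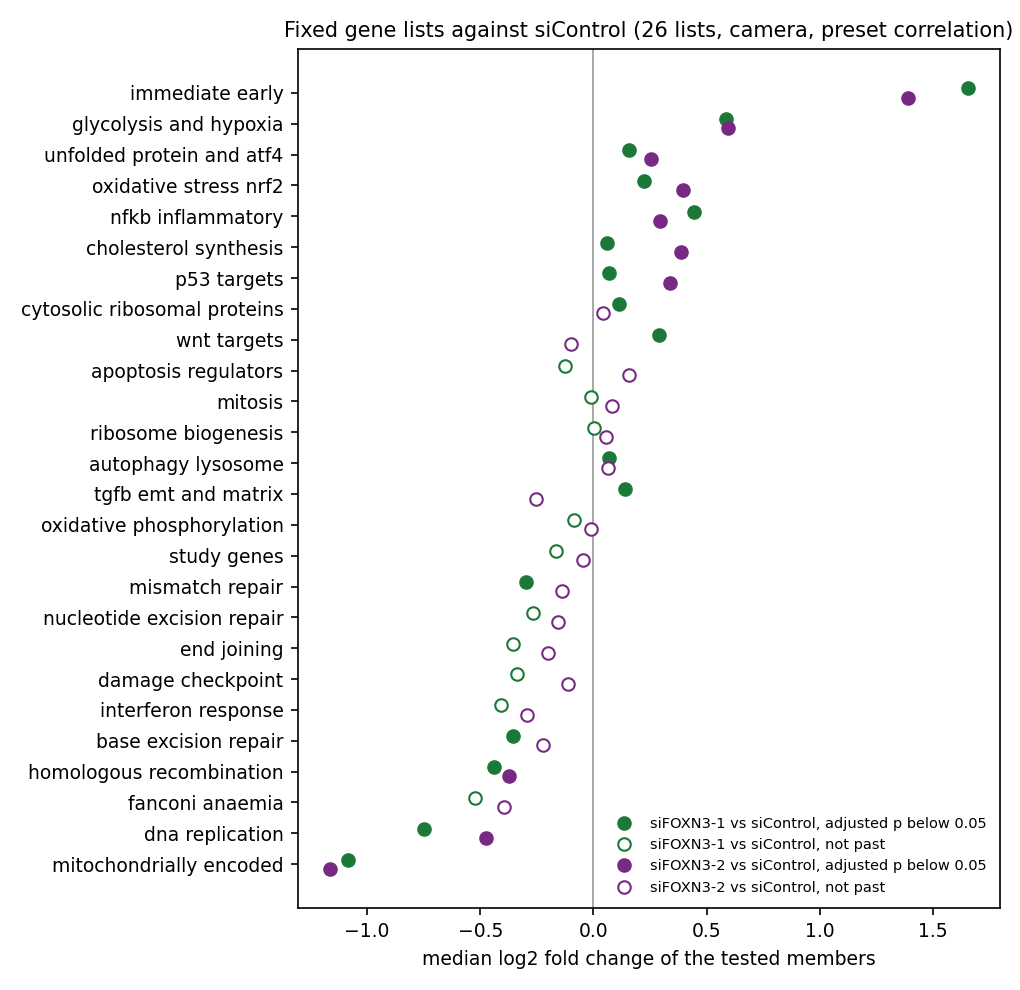
Median log2 fold change of the tested members of 26 gene lists with siFOXN3-1 and siFOXN3-2 against siControl, with filled symbols for lists past an adjusted p of 0.05. Immediate early genes had the highest medians, 1.66 and 1.39, and mitochondrially encoded genes the lowest, -1.09 and -1.16.

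Of the markers of other cell types, 3 passed the expression filter, FBLN1, ACTA2 and AGER. Immune cell markers (19 in the table, none past the expression filter) summed to 4.04 FPKM in siControl, 2.68 FPKM with siFOXN3-1 and 5.77 FPKM with siFOXN3-2. LYZ, a lysozyme of myeloid cells, averaged 0.635 ± 0.373 FPKM in siControl, 0.0418 ± 0.0199 FPKM with siFOXN3-1 and 1.46 ± 0.209 FPKM with siFOXN3-2 (SD, n = 3). The myeloid adaptor TYROBP averaged 0.134 ± 0.0330 FPKM in siControl and 0.450 ± 0.138 FPKM with siFOXN3-2, the leukocyte antigen PTPRC 0.0547 ± 0.0274 and 0.160 ± 0.0340 FPKM, and both were listed at 0 in all 3 siFOXN3-1 samples. Fibroblast markers (13 in the table, FBLN1 and ACTA2 tested) summed to 8.93, 6.95 and 9.63 FPKM. LYZ, TYROBP, PTPRC, COL1A2 and COL3A1 were chosen after their values were seen. The collagen genes COL1A2 and COL3A1 averaged 0.916 ± 0.263 and 0.786 ± 0.175 FPKM with siFOXN3-2, against 0.0155 ± 0.00677 and 0.0919 ± 0.00554 FPKM in siControl and 0.0194 ± 0.00756 and 0.0452 ± 0.0197 FPKM with siFOXN3-1. FBLN1 fell from 5.74 ± 0.213 to 4.89 ± 0.0898 and 4.23 ± 0.238 FPKM and ACTA2 from 1.85 ± 0.147 to 1.23 ± 0.0887 and 1.31 ± 0.148 FPKM, although under quantile normalization FBLN1 had a log2 fold change of 0.01 with siFOXN3-1. Endothelial markers (10 in the table, none tested) summed to 1.44, 1.28 and 0.917 FPKM. Lung epithelial markers (16 in the table) summed to 5.98, 4.37 and 4.42 FPKM, and AGER, the only member tested, had 2.89, 2.39 and 2.26 FPKM.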

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

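The tests of GC content, of siControl handling, of both seed motifs, of RNA from other cells and of smaller shared changes and the interval of the slope were chosen after the results were seen. Between the 2 siRNAs, which target the same gene, the change against siControl differed for 4590 genes by limma's test of the difference. Of these, 2023 had changed in the same direction with both siRNAs. For 185 genes the siRNAs acted in opposite directions and also differed from each other, 65 of them higher with siFOXN3-1 and lower with siFOXN3-2, such as MTPN and CCND1, and 120 the reverse, such as PPIP5K2. Among gene lists, 11 differed between the siRNAs at the preset correlation and none with an estimated correlation.

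No label gives a batch, so a separate handling of the siFOXN3-1 and siFOXN3-2 samples cannot be told apart from a difference between the siRNAs. That difference may in part reflect seed-matched off-target effects. The 3' UTR 7-mer most depleted with siFOXN3-2 against siFOXN3-1, AATAACA (1584 genes, z = -20.35), was also depleted against siControl (z = -10.52, beyond the 5.09 of 200 permutations) and not with siFOXN3-1 (z = 0.91), although without adjustment 43.6% of its genes were lower with siFOXN3-2 than with siControl against 40.3% of the others. For siFOXN3-1 the leading 7-mer, GATTAGA (847 genes), had z = 9.66 for siFOXN3-2 against siFOXN3-1, beyond the 5.01 of permutations, and z = -4.91 for siFOXN3-1 against siControl, within the 5.12 there, so an effect of this seed stays open, and the siRNA sequences are not given in the sources used here. A deeper knockdown with siFOXN3-2 would make shared changes larger with that siRNA and was not the whole cause, since 1180 of the 2023 shared genes that differed changed less with it (856 of 1657 under quantile normalization), but it stays open as a part, with a slope over 6183 shared genes of 0.970 and a 95% interval of 0.919 to 1.02 from a jackknife over the samples. RNA of other cells stays open, since immune and fibroblast markers of the fixed lists gained at most 1.42 FPKM from siFOXN3-1 to siFOXN3-2, but S100A9, chosen after its values were seen, gained 3.41 FPKM, against a median gain of 2.09 FPKM among the 3227 higher genes.

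The shared change with both siRNAs was weighed against technical causes and against the loss of FOXN3. Fold changes followed GC content (Spearman correlation -0.28 over 10685 protein-coding genes in the average of both). From the lowest to the highest of 6 GC bins, medians ran from -0.05 to -0.37 with siFOXN3-1 and from 0.08 to -0.29 with siFOXN3-2. This trend was too small to make up the immediate early median, 1.55 after correction and 1.52 before, which therefore decides nothing for smaller changes. After correction, 5309 of 6183 shared genes (85.9%) kept their call and direction. Of 3686 shared falling genes, 82.1% held neither leading 7-mer in the scanned 3' UTR, against 79.5% of all scanned genes (a ratio of 1.03). Most shared falling genes thus held no match to these 7-mers there, but the ratio cannot weigh seeds as a cause. The 7-mers were picked for a difference between the siRNAs. Each lay within the permutations with the other siRNA (AATAACA z = 0.91 with siFOXN3-1, GATTAGA z = 0.43 with siFOXN3-2). Their genes could therefore hardly gather among shared falls, and effects of seeds on shared falls stay open. In the average of both, the most depleted 7-mer, ATAACAA, reached z = -5.09, just within the 5.12 of permutations. It is a shifted form of AATAACA, which came next at z = -4.94, and does not stand for a separate seed. For ATAACAA, z was -10.49 with siFOXN3-2 against siControl and -19.74 for siFOXN3-2 against siFOXN3-1. A separate handling or harvest of the siControl cells cannot be told apart from the loss of FOXN3, since the correlation of 0.870 between the siRNAs rests on the same 3 siControl samples and no label gives a batch. The traces of white blood cell genes followed another pattern, with S100A9 at 0.938 FPKM in siControl, 3.41 FPKM with siFOXN3-2 and 0 with siFOXN3-1.

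Other splits of the samples bear on these counts. In 1 of 100 drawn splits of the 9 samples into 3 groups, the real one, the average of both siRNAs reached 8589 genes, and the highest other, which kept the 3 siControl samples together, gave 7177. Likewise 1 of 100 reached 6183 shared genes, with 5532 as the highest other, so the real split ranked first for both counts. Since the replicates may be technical, these splits cannot exclude a chance difference between cultures. Splits that did not keep the siControl samples together gave at most 835 and 229 genes. For single siRNAs the 10 splits of 6 samples are too few for a share under 0.05, with 8220 genes for siFOXN3-1, 8049 for siFOXN3-2 and 4590 between the siRNAs in 1 of 10 splits each and 0 as the highest other in each.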

How the results depend on the processing

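The alternatives with a GC correction, with voom on recovered reads and with protein-coding genes only were chosen after seeing the data. Over 24 alternatives, 445 results of named genes kept their direction and side of the threshold in 10453 cases, lost the call in 117, gained it in 2 and reversed in 5. For 104 list results, also over 24 alternatives, these numbers were 2363, 76, 50 and 3. Genes that were not tested had no value, so the filter of 5 covered 353 gene and 100 list results and protein-coding genes alone covered 434 gene results. All reversals came with quantile normalization, and their cause was not tested. They were AGER in the average of both siRNAs (0.00438), FBLN1 with siFOXN3-1 (0.0143), RPL5 in the average (-0.0312), with siFOXN3-1 (-0.0571) and with siFOXN3-2 (-0.00525), and the median of the ribosomal protein list in the average (-0.0969), with siFOXN3-1 (-0.109) and between the siRNAs (0.0492).

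Counts moved by more than 1.5 times in these cases. A filter on a mean FPKM of at least 5, which left 7101 genes to test, gave 4708 genes for siFOXN3-1, 4716 for siFOXN3-2, 4905 for the average and 3495 shared, and this filter cannot give FOXN3 a value. A log2 threshold of 1 gave 887, 777, 734 and 517, and 45 between the siRNAs, a threshold that leaves out smaller changes by construction. With an estimated correlation, 3 lists passed for siFOXN3-1, 0 for siFOXN3-2, 0 for the average and 0 between the siRNAs. Quantile normalization left 10 lists for siFOXN3-1, and without a filter 17 passed for siFOXN3-2 and 19 between the siRNAs; the cause was not tested. The homologous recombination list no longer passed with the filter of 5 (-0.298, adjusted p = 0.0867) or with an estimated correlation (-0.408, adjusted p = 0.274). The log2 threshold was run on gene counts alone, voom was not run on the lists, and the estimated correlation applies to lists alone.

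Without 1 sample at a time, FOXN3 ranged from -1.46 to -1.41 with siFOXN3-1 and from -1.66 to -1.59 with siFOXN3-2. Gene counts ranged from 7536 to 8453, 7249 to 8115, 7714 to 8540 for the average, 3315 to 4307 between the siRNAs and 5555 to 6062 shared. Passing lists ranged from 15 to 16, 10 to 11, 11 to 11 and 10 to 11, and the homologous recombination median from -0.43 to -0.38. With the replicate number as a replicate block, 7668, 7422, 8019, 3465 and 5686 genes passed, and 4 named gene results and no list lost their call. Deviations from group means correlated at -0.28 to 0.0528 for the same number and at -0.16 to 0.274 for others. These values gave no sign of pairing by number, but with 3 samples per group they cannot exclude it. In simulations, changes of 0.5 were recovered less often (76.7 and 83.1%) than changes of 1. These simulations used the fitted spread between samples and did not model read depth.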

Other observations

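The gene families here and the list tests run on them were chosen after their values were seen, so counts and medians are given without the p-values of those tests, and the tests of the AU-rich motif were set before theirs. Histone genes of the replication-dependent clusters rose with both siRNAs. Of 33 tested, 22 rose and 1 fell with siFOXN3-1 (median log2 fold change 0.73). With siFOXN3-2, 23 rose and 2 fell (median 0.78). H2BC11, a histone H2B, rose from 8.33 ± 0.882 FPKM in siControl to 65.96 ± 1.74 and 57.6 ± 2.32 FPKM, and the linker histone H1-2 from 95.4 ± 10.99 to 399 ± 34.1 and 423 ± 47.6 FPKM (SD, n = 3). Histone paralogs share reads, and most of their transcripts lack the poly(A) tail that these libraries select. Of 12 KLF transcription factor genes, 8 rose and 1 fell with siFOXN3-1 and 8 rose and 0 fell with siFOXN3-2, with medians of 0.55 and 0.31, KLF4 going from 5.11 ± 0.109 to 15.9 ± 1.16 and 16.3 ± 0.1397 FPKM.

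Of 20 host genes of small nucleolar RNAs (SNHG), 13 rose and 2 fell with siFOXN3-1 and 15 rose and 1 fell with siFOXN3-2, with a median of 0.35 for each. SNHG5 rose from 77.7 ± 5.99 to 211 ± 15.6 and 172 ± 20.1 FPKM, and SNHG11 fell from 3.86 ± 0.156 to 1.13 ± 0.00288 and 1.603 ± 0.1799 FPKM. Of 325 ZNF genes, most of which encode zinc finger transcription factors, 212 fell and 29 rose with siFOXN3-1 and 166 fell and 45 rose with siFOXN3-2 (medians -0.37 and -0.21). All 4 families kept these directions of the median under median-ratio, quantile and sum scaling, the ZNF medians shrinking to -0.13 and -0.06 under quantile normalization. The mitochondrial ribosomal RNA MT-RNR2 rose from 3178 ± 116 to 4416 ± 280.1 and 4381 ± 379.9 FPKM, while MT-RNR1, the other such RNA, had 802 ± 10.8 FPKM in siControl, 763 ± 59.5 FPKM with siFOXN3-1 (log2 fold change -0.07, adjusted p = 0.377) and 696 ± 41.3 FPKM with siFOXN3-2 (-0.21, adjusted p = 0.0259), and polyadenylated libraries measure both only in part.

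An AU-rich 3' UTR motif went with higher fold changes after adjustment for UTR length, GC content and expression, and the 7-mer TATTTAT was the most enriched of 16173 in the average of both (3815 genes, z = 11.62, beyond the 5.12 of 200 permutations), with a mean adjusted log2 fold change of its genes 0.07 above that of all scanned genes. Without adjustment, 36.4% of its genes were lower and 31.6% higher, against 52.7% and 17.7% of the others, a difference that was not tested. The best of 18 other orders of the same bases that do not hold ATTTA, TATATTT, reached z = 4.38, within the 5.12 of permutations. The orders TTATTTA and ATTTATT, which hold ATTTA, reached z = 8.11 and 7.71. Since TATTTAT was picked as the highest of all 7-mers, no other order could exceed it, so a part of base composition stays open. The immediate early, inflammatory and hypoxia lists alone did not account for the motif, since without their 74 members z was 10.88, beyond the 5.78 of permutations. A response to the loss of FOXN3 and one to handling of the siControl cells stay open here as for the shared change.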
